A study of Mus musculus with 2 samples.

How the data were processed

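Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map c-Fos on DNA in mouse bone marrow-derived mesenchymal stem cells. These are stromal cells that can form bone, cartilage and fat. The cells lacked p53, a tumour suppressor, and expressed c-Fos, a transcription factor that pairs with Jun proteins to form AP-1. Per the labels, the cells had been passaged fewer than 20 times. For the ChIP, 50000000 cells were fixed and 10 ug of an anti-c-Fos antibody was used. The data hold no check of whether this antibody recovers c-Fos alone, so c-Fos peaks here means peaks obtained with it. The series holds 1 c-Fos ChIP library and 1 input library, that is, DNA that was not immunoprecipitated. Samples were grouped by the antibody given in the labels.

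The 1 file used here is the list of c-Fos ChIP peaks. It gives a sequence name, a start, an end, a peak name and a score for each peak. The score is the value deposited by the authors for each peak, and the file does not state its scale. It was used only to describe, rank and filter peaks within the list, and it is not a measure of peak height or of how strongly c-Fos was bound. A score that rests on a p-value would also depend on read depth and on the width of the peak. The submitters' processing notes name CASAVA 1.8.2, MACS 1.4.1 and the mouse build mm9, without saying what each was used for. The peak names in the file carry the prefix that MACS writes. The aligner, the read filters, the peak threshold and whether the input library was the control in peak calling are not given in the sources used here. The lowest deposited score was 50.01. Sites of lower score are not in the list. Peaks did not overlap (0 overlapping pairs), and the smallest gap between neighbours was 7 bp.

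Read counts per library and signal tracks were not used here, so the sequencing depth is unknown and no peak height can be given. With 1 ChIP library there is no replicate error. All intervals and p-values below describe the positions, widths and scores within this list. They cover counting error or random placement only, peaks are not independent replicates, and none of them measures variation between cultures.

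Positions are given 1-based in mm9, as in the file. The gene table at hand is on GRCm38.p6. Coordinates were not converted between builds, so 0 peaks were joined to genes, and no gene, promoter or sequence motif is reported. The planned comparisons with transcription start sites, with gene lists, with the Sox9 region and with sequence motifs were therefore not run. Comparisons that had been planned against the mm9 sequence length used the span between the first and the last peak centre of each chromosome instead, and no test was made of peak numbers per chromosome. The rule for named items, fixed before the data were examined, gave the 10 peaks of highest score by position where no annotation of the build is at hand. The widest peaks, the runs of peaks, the densest windows and the longest stretches without peaks were chosen after their values were seen.

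Peaks per Mb were computed for chromosomes 1 to 19 and X with exact Poisson 95% intervals. Intervals of medians came from order statistics and intervals of shares are Wilson intervals. Clustering was tested on distances between neighbouring peak centres against 1000 random placements between the first and last peak of each chromosome (two-sided; the smallest p that these can give is 0.002). A run of peaks was a set in which each neighbouring pair of centres lay within 10 kb. Correlations across peaks were tested with 100000 permutations, whose smallest p is 1e-05. Median differences between sets of peaks were tested with 100000 permutations as well, two-sided, with Benjamini-Hochberg adjustment over the 5 comparisons made, and over 19 for the median score of each autosome against the others. These comparisons of medians were chosen after the values were seen. The procedures were tested on simulated positions for 10850 peaks. With uniform positions, the share of neighbours within 10 kb was 0.998 times the random share. With 20% of the peaks planted next to another, it was 4.98 times.

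The alternatives were a score of at least 100, leaving out the widest 5% of peaks (1312 bp or more), and a distance of 50 kb. Further alternatives were added after the data were seen. These were chromosomes 1 to 19 and X alone, leaving out X, leaving out the 5 longest stretches without peaks on each chromosome, moving each peak at random within 500 kb, and joining peaks whose edges lay within 2 kb. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.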

Results

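The data comprised 1 c-Fos ChIP-seq library and 1 input library from p53-deficient mouse bone marrow mesenchymal stem cells expressing c-Fos. The title of the series places them in a study of c-Fos and Sox9 in chondroblastic osteosarcoma, a bone tumour that forms cartilage-like matrix. The measurement asks where c-Fos was bound in these cells, as far as the antibody is specific to it. The labels name no cells without c-Fos, no second antibody and no replicate, so the comparisons below are between regions of the genome within 1 peak list. Which genes lay near the peaks, Sox9 among them, was not analysed here, because the gene table at hand is on another genome build.

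The list held 10870 c-Fos peaks, which together covered 10.6 Mb of mm9. The autosomes held 10785 of them (99.2%) and chromosome X held 65 (0.598%). Chromosome Y held 1, and 19 lay on sequence not assigned to a position on a chromosome. The median width of the peaks was 949 bp (95% interval 946 to 952 bp), and the middle of the distribution ran from 864 bp at the lower quartile to 1039 bp at the upper quartile. The authors' score, their own value for each peak, had a median of 101 (95% interval 99.5 to 103) and ranged from 50.01 to 1685.19. Of the 10870 peaks, 1700 (15.6%) scored under 60, while 2023 scored at least 200, 228 at least 500 and 12 at least 1000.

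The 10 sites of highest score lay on 6 chromosomes, with 3 on chromosome 6, 2 on chromosome 14 and 2 on chromosome 17. The highest was on chromosome 6 from 52775173 to 52776429, with a score of 1685.19 and a width of 1257 bp. Its nearest neighbour in the list was 239 kb away. The second was on chromosome 17 from 39979582 to 39986286, with a score of 1339.87. At 6705 bp it was also the widest peak in the list. The other two on chromosome 6 ran from 91438074 to 91439770 (score 1217.03) and from 72876390 to 72877682 (score 1187.98). The site on chromosome 8 from 26575638 to 26576781 scored 1107.84, and the site on chromosome 3 from 123260986 to 123262161 scored 1075.56. The other site on chromosome 17 ran from 48494984 to 48496238 and scored 1071.67. On chromosome 14, the site from 47991077 to 47992254 scored 1066.28 and the site from 51708164 to 51711001 scored 1052.69. The site on chromosome 11 from 68853435 to 68855800 scored 1060.40. For this library alone these are ranks, with no replicate check and no check against repeated or multicopy sequence.

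Sites of higher score were wider. With the peaks divided into 5 equal groups by score, the median width was 838 bp in the lowest group and 901, 955, 1008 and 1102 bp in the following groups. Across the 10870 peaks, Spearman's rho of score and width was 0.70 and Pearson's r was 0.52 (permutation p = 1e-05 for each, two-sided, the smallest that the permutations can give). Peaks are not independent replicates, so this describes the list. The 10 peaks wider than 3 kb did not follow this order closely. Of these, 7 scored below 200 and 3 below the list's median, and 2 lay on unplaced sequence. Among them were a pair on chromosome 6, from 47687055 to 47691274 (4220 bp, score 131) and from 47717291 to 47723650 (6360 bp, score 150). Another pair lay on chromosome 1, from 172993660 to 172997523 (3864 bp, score 129) and from 173008950 to 173012712 (3763 bp, score 104).

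**Figure D1:**
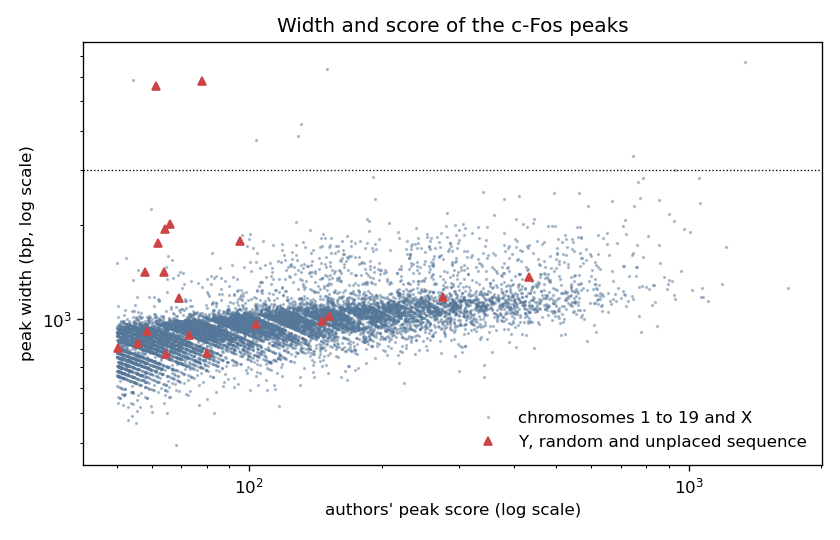
Width in bp against the authors' score for each of the 10870 c-Fos peaks, both on log axes; dots are peaks on chromosomes 1 to 19 and X, triangles are peaks on Y, random and unplaced sequence, and the dotted line marks 3 kb. Width rises with score (Spearman's rho 0.70), and 10 peaks lie above the dotted line, 7 of them with scores below 200.

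The chromosomes differed in how densely c-Fos peaks lay on them. Chromosome 19 had the highest density, 6.57 peaks per Mb of span (95% Poisson interval 5.93 to 7.27). Chromosome 11 followed with 6.32 (5.88 to 6.79), chromosome 17 with 5.89 (5.40 to 6.41) and chromosome 6 with 5.59 (5.21 to 5.98). The median autosome had 4.52. At the low end were chromosome 1 with 3.20 (2.95 to 3.46), chromosome 7 with 2.93 (2.67 to 3.22) and chromosome 12 with 2.41 (2.13 to 2.70). Density on chromosome 19 was thus 2.73 times that on chromosome 12. The intervals of these 3 low chromosomes did not reach those of the 4 high ones, but all were picked by their values. Poisson intervals treat peaks as independent. With the clustering described below, they are too narrow for comparing chromosomes. The top rank depended on the score: among peaks scoring at least 100, chromosome 11 was the densest, with 3.34 per Mb against 3.15 on chromosome 19. Median scores were not shown to differ between autosomes. The highest were 111 on chromosome 6 and 110 on chromosome 17, against 101 on the other autosomes in each case. With adjustment over the 19 autosomes, 0 passed the permutation test and 2 had an unadjusted p under 0.05 (chromosome 6, p = 0.00285, adjusted p = 0.0541; chromosome 17, p = 0.0319, adjusted p = 0.303). Among peaks scoring at least 100, a filter on the score itself, chromosome 6 passed, with a difference of 23.1 (adjusted permutation p = 0.00095).

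Chromosome X held few c-Fos peaks. It had 0.413 peaks per Mb (95% Poisson interval 0.319 to 0.526), a density 10.9 times lower than on the median autosome (8.58 to 14.2) and 5.83 times lower than on chromosome 12, the sparsest autosome. The X sites that were listed also had lower scores and were narrower. Their median score was 74.4, against 101.6 on the autosomes (permutation p = 0.0197, adjusted p = 0.0246), and their median width was 845 bp against 950 bp (permutation p = 2e-05, adjusted p = 3.33e-05). Of the X sites, 16 of 65 (24.6%, Wilson 95% interval 15.8 to 36.3) scored at least 100. On single autosomes that share lay between 46.7% and 55.3%. At a score of at least 100 the density on X was 20.6 times lower than on the median autosome, with an interval of 12.7 to 36.0 from those 16 peaks. When the 5 longest stretches without peaks were left out of every chromosome, it was 6.15 times lower (4.82 to 7.97). That step takes more from a sparse chromosome and so raises X. The longest stretch was 32.0 Mb on X, against at most 10.8 Mb on an autosome (chromosome 14). The number of X chromosomes in these cells is not given in the sources used here.

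**Figure D2:**
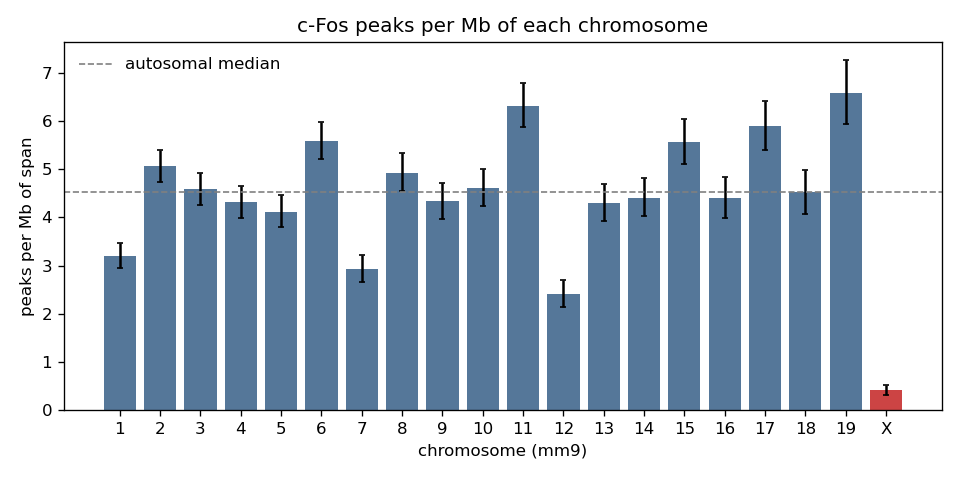
c-Fos peaks per Mb between the first and last peak of each chromosome (mm9), with exact Poisson 95% intervals as error bars and the autosomal median of 4.52 as a dashed line. The autosomes range from 2.41 on chromosome 12 to 6.57 on chromosome 19, and chromosome X has 0.413.

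Sites were grouped along the chromosomes. The median distance between neighbouring peak centres was 65.1 kb, against 150 ± 1.48 kb (SD over 1000 random placements). Neighbours within 10 kb made up 15.3% of the pairs, 3.32 times the 4.60% ± 0.210 of random placement, and neighbours within 50 kb made up 43.8%, against 20.9% ± 0.352. Each of these differed from random placement with p = 0.002, two-sided, the smallest that this permutation can give. Gaps in the assembled sequence were not left out of the random placements, which can enlarge these differences. Runs of at least 3 peaks, each within 10 kb of the next, numbered 241 and held 825 peaks, where random placement gave 22.5 ± 4.72 runs. Runs of at least 5 numbered 14, where random placement gave 0.065 on average and at most 2. Part of this excess followed the density of the surrounding region. When each peak was instead moved at random within 500 kb, 80.8 ± 8.25 runs of at least 3 and 2.29 ± 1.34 runs of at least 5 arose. With peaks whose edges lay within 2 kb also joined, there were 124 runs of at least 3 against 67.1 ± 7.72 (1.85 times, permutation p = 0.002), and 5 runs of at least 5 against 1.69 ± 1.19 (permutation p = 0.038). The moved positions were not joined again, so they could lie closer together than joined peaks can, which can lower these excesses.

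**Figure D3:**
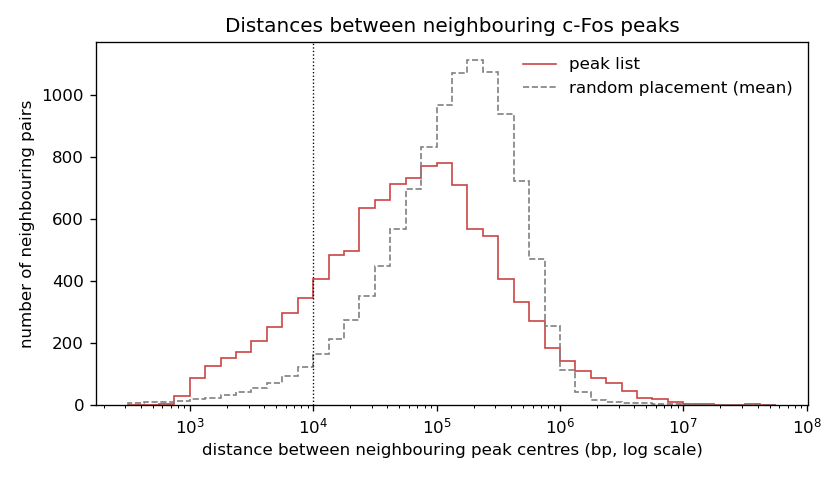
Number of neighbouring peak pairs by the distance between their centres in bp (log axis) for the c-Fos list (solid line) and the mean of random placements (dashed line); the dotted line marks 10 kb. Below 750 bp the list holds fewer pairs than random placement, since its peaks do not overlap while randomly placed points may lie at any distance. Above that it exceeds random placement at short distances, with 15.3% against 4.60% of pairs within 10 kb, and again at distances above 1 Mb.

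The run with the most peaks was on chromosome 13 from 23517243 to 23545795, where 9 peaks lay within 28.6 kb, with scores from 57.71 to 230.79. Neither this run nor the others named here were checked against repeated or multicopy sequence. A run of 8 peaks on chromosome 3, from 88294461 to 88326373, reached a score of 742.12. Runs of 6 peaks lay on chromosome 15 from 76020119 to 76044449, where the highest score was 861.62, on chromosome 2 from 44807957 to 44833829 and on chromosome 3 from 108562211 to 108585146. Of the 2565 windows of 1 Mb between the first and last peaks, 732 (28.5%) held no peak and 24 held at least 20. The fullest window was on chromosome 19 from 5000001 to 6000000, with 29 peaks and a median score of 90.4. The next was on chromosome 8 from 124000001 to 125000000, with 28 peaks and a median score of 181. Of the 5 stretches over 10 Mb without a peak, 4 were on chromosome X, and the longest of these ran for 32.0 Mb from 101684163 to 133707811. The fifth was on chromosome 14 from 106563440 to 117327339.

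**Figure D4:**
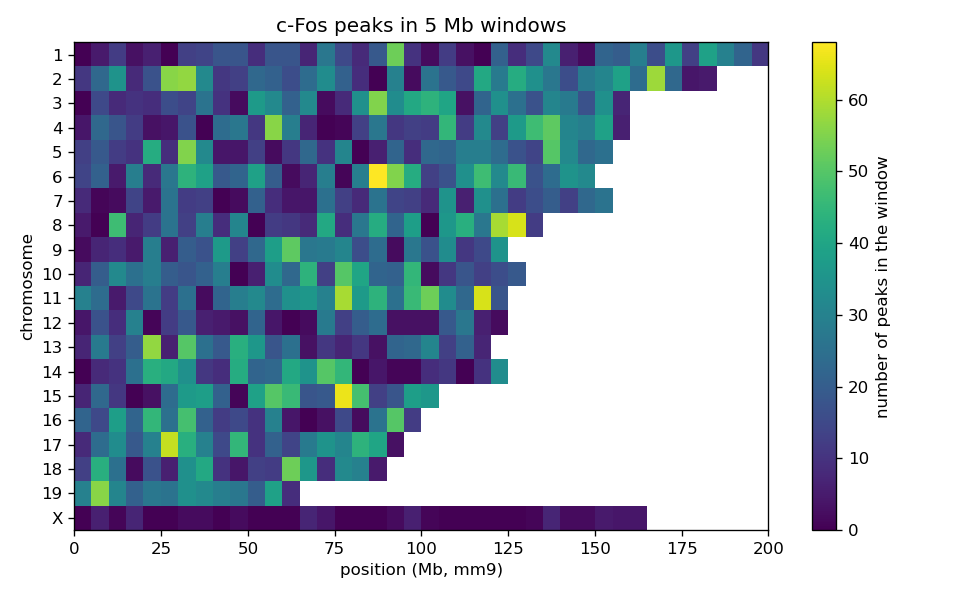
Number of c-Fos peaks in windows of 5 Mb along chromosomes 1 to 19 and X (mm9 position in Mb), with brighter colours for more peaks and white beyond the last peak. Chromosome X holds few peaks throughout, with 65 in all, and the number of peaks varies from window to window along the autosomes.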

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

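Of 54 recomputed values, 44 stayed within the main value's interval, within 1.5 times a count, or on the same side of a test's threshold. Another 8 moved, 1 lost its call, 1 gained one, and none changed direction. Some of these outcomes were set by the filter itself, as a filter on score must raise the median score. A tested value could also shrink and still count as the same, so the tally does not measure stability. A score of at least 100 left 5507 peaks, with a median width of 1028 bp and a median score of 167. It lowered the ratio of X to autosomal density from 0.0914 to 0.0486. Without the widest 5% of peaks the median width was 942 bp and the median score 97.6. Leaving out the 5 longest stretches without peaks raised the ratio for X to 0.163. The eighth was the run of 9 peaks on chromosome 13, of which 4 scored at least 100. The lower score of X peaks lost its call at a score of at least 100 (difference -18.7, permutation p = 0.45), a filter on the tested value that left 16 X peaks, so this says nothing of its stability. The excess of the median score of chromosome 6 over other autosomes passed there (23.1, adjusted permutation p = 0.00095), but not without the widest 5% (6.92, adjusted permutation p = 0.262) or over all peaks (10.2). The excess of neighbours within 10 kb lay between 1.42 and 3.98 times random under the alternatives tried, each with a permutation p of 0.002. The lowest value came from joining peaks within 2 kb and moving them within 500 kb without joining again, a step that itself lowers the value. The alternatives set out beforehand that need the mm9 sequence or annotation were not run: those for peak annotation, motif shares, gene lists, the Sox9 region, soft-masked length and placement by distance to start sites. The depth of the library is unknown, so how many sites fell below the lowest score of 50.01 cannot be estimated. No paired analysis was possible because the series holds 1 ChIP library.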

Other observations

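All tests in this part were chosen after the data had been examined. Peaks with a neighbour within 10 kb scored higher than the others, with a median of 109 for 2965 peaks against 99.0 for 7885 (permutation p = 2e-05, adjusted p = 3.33e-05). The permutation treated peaks of the same run as independent, so this p can be too small. Across the 19 autosomes, peak density and the median score had a positive correlation that was not firmly established. Pearson's r was 0.47 (permutation p = 0.0427, unadjusted) and Spearman's rho was 0.44 (permutation p = 0.0611, unadjusted). Without chromosomes 12 and 19, the farthest from the median density, r was 0.64 (permutation p = 0.00552) and rho 0.53 (permutation p = 0.0314). Of these, chromosome 19, the densest, went against the trend, with a median score of 97.4 against 101.7 on the other autosomes. Chromosome 12, the sparsest, went with it (97.8 against 101.7). Chromosomes are not independent samples. The 10 peaks on unplaced sequence had widths from 774 to 5795 bp, with a median of 1763 bp against 949 bp on chromosomes 1 to 19 and X (permutation p = 1e-05, the smallest possible, adjusted p = 3.33e-05), but their median score of 65.5 against 101 did not pass the test (permutation p = 0.161). The unlocalised sequence of chromosome Y held 5 peaks, with scores from 58.64 to 432.53.

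Few peaks lay on chromosome X, and those were of low score. Long stretches without peaks do not account for this alone: with the 5 longest left out of every chromosome, X had 0.931 peaks per Mb and the sparsest autosome 3.10. Weaker enrichment over the whole of X is a candidate explanation, since the X peaks that were listed had lower scores (median difference -27.2, permutation p = 0.0197). The score is not a peak height, and X peaks were also narrower, so lower scores do not establish weaker binding. Neither the number of X copies in these cells nor read counts were at hand. A lower dose of X DNA, its chromatin state and less c-Fos on X therefore all stay open. Whether a lower dose alone could give a density 10.9 times lower than on the median autosome was not tested.

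Neighbouring peaks lay closer than random placement. Broad regional differences in density are part of it. When each peak was moved within 500 kb, which keeps only broad regions, the share within 10 kb was still 1.89 times the random share (permutation p = 0.002). The move smooths out dense regions narrower than 500 kb, so it cannot tell whether such regions account for the rest. Splitting of a broad region into several peaks could also add close pairs. After joining peaks within 2 kb the excess over the moved positions was 1.42 times (permutation p = 0.002). The moved positions were not joined again, so they could lie closer together than joined peaks can, which lowers this value. Regions without planted close pairs were also simulated, reaching 1 Mb to either side of a centre. They gave 1.07 times when moved and 0.772 times when joined and moved. This fall arose without split regions, so the fall from 1.89 to 1.42 in the list does not measure splitting. Before moving or joining, the simulated regions had 8.40% of neighbours within 10 kb, against 15.3% in the list. Narrower regions were not simulated. Groups of separate c-Fos sites, as in gene-dense or regulatory regions, may remain as a hypothesis, and it was not tested against an annotation.

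The 10 peaks wider than 3 kb are a pattern to check against repeats and multicopy genes. Of these, 7 lay outside the top 20% of scores, which began at 192, while 4 of the 5 next widest lay within it, so the share depends on the width chosen. Sequence not placed on a chromosome held 2 of the 10, and whether it accounts for those 2 stays open. A candidate explanation is reads from many genomic copies collapsed onto 1 place in the build, as for the peak of 6705 bp on chromosome 17, but this needs the mm9 sequence and was not tested. The same applies to the runs of close peaks, such as the 9 on chromosome 13.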
